A study of Mus musculus with 40 samples.

How the data were processed

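A deposited value exists for each gene or region and library. The authors' processing notes name genome build mm10 and DESeq2 for all samples. For alignment they name STAR 2.6.0 in the HSPC and restoration RNA-seq, STAR and Bowtie2 without versions in CUT&Tag and in the DZNeP RNA-seq, and Bowtie2 and Picard in ATAC-seq. The values are signal, deposited by the authors as read counts divided by a size factor for each library. Multiplied by that factor, 100% of values were whole reads within 0.02 reads. CUT&Tag used the NovoNGS kit. Duplicated gene identifiers were dropped (38, 38 and 42 entries in the HSPC, restoration and DZNeP tables), and 2 identifiers in each had no symbol.

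Each comparison was fitted alone with limma 3.58.1 with an intensity trend on log2(value + 1), for genes or regions with a mean above 1, without a block, two-sided, with a Benjamini-Hochberg adjusted p below 0.05. The plan fixed before the data were examined put edgeR first for whole counts and this limma test first for normalised values, which these are. The edgeR 4.0.16 test with TMM scaling on recovered reads was therefore added as an alternative after the unit was known. DESeq2 1.42.0 and edgeR with RLE scaling were part of the plan. Tests on recovered reads leave out restoration replicate 2 of RNA-seq, restoration replicate 2 of H3K4me2 and restoration replicate 3 of H3K27me3. For H3K4me2 those tests hold 1 restored library against 2 knockdown libraries. Calculations used R 4.3.3, GenomicRanges 1.54.1 and data.table (version 1.17.8), and figures Python 3.11.15 and matplotlib 3.10.9.

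Fold changes are given as log2 of the first group over the second, with SE from limma. The SE and the p-values built on it draw on features of similar signal, so they can understate the spread of a single feature. Means and SDs are of the deposited values. A gene or region rose or fell if its adjusted p was below 0.05. Libraries did not overlap if every value of a group lay above every value of the other.

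The 26 gene lists were written before the data were examined: cytosolic ribosomal proteins, ribosome biogenesis factors, RNA polymerase I machinery, mTOR pathway negative regulators, mTORC1 components and amino acid transporters, stem and progenitor cell genes, granulocyte genes, monocyte and macrophage genes, mast cell and basophil genes, erythroid genes, megakaryocyte genes, B cell genes, T and NK cell genes, dendritic cell and MHC class II genes, stromal and endothelial genes, cell cycle genes, p53 target genes, interferon-stimulated genes, KMT2 complexes and H3K4 demethylases, Polycomb repressive complex 2, integrated stress response genes, glycolysis and hypoxia genes, cholesterol biosynthesis genes, developmental Polycomb target genes, methionine cycle genes and mitochondrially encoded genes. They were tested with the limma camera test with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison with at least 5 measured members. Camera asks whether a list moved more than other genes, and fry, an alternative, whether its members moved at all. With a correlation estimated from the data only the B cell and the MHC class II lists on restoration were called. The Polycomb repressive complex 2 list also holds Kdm6b, an H3K27 demethylase gene that is not part of that complex.

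The names given follow a rule written beforehand, of which the text prints a part. Kmt2d, Ddit4, Myc, Ezh2 and Kdm6a are always named. To these come the 8 largest rises and 8 largest falls among called genes of above median abundance whose libraries did not overlap, and from lists with a called test or at least 3 called members the 3 with the smallest adjusted p and 1 that moved the other way. For marks the 5 largest changes each way are named.

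Regions were assigned to genes whose span they overlapped or lay within 2 kb of. The plan named transcription start sites, but the reference held no strand. ATAC-seq starts were shifted by 1, and CUT&Tag coordinates were used as given, since their base is not stated. Overlaps of calls were tested with Fisher's exact test, two-sided, and marks at genes with 100000 label shuffles across genes (random seed 1), with 1 value per gene, the mean over its regions.

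In a self-test, 200 features per comparison were changed in simulated counts. The changed features were drawn from those above the median mean, and every feature was simulated independently. The rates below therefore do not cover less abundant features or features that move together between libraries. Changes of 2-fold were recovered in 100% of cases in each RNA-seq comparison and for H3K4me2, 94% for H3K4me1, 89% for H3K27ac, 82% for H3K27me3 and 0% for ATAC-seq. Changes of 1.5-fold were recovered in 77% in HSPCs, 100% in both AML RNA-seq comparisons, 62% for H3K4me1, 82% for H3K4me2, 61% for H3K27ac and 29% for H3K27me3. False calls numbered 16 of 193 calls in HSPCs, 10 of 210 on restoration, 12 of 212 with DZNeP, 4 of 160 for H3K4me1, 14 of 196 for H3K4me2, 4 of 154 for H3K27ac and 1 of 112 for H3K27me3, so the share in HSPCs, with DZNeP and for H3K4me2 lay above 0.05.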

Results

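Gene expression, chromatin accessibility and histone marks were measured in mouse blood cells with low or restored Kmt2d, the gene of a histone H3K4 methyltransferase. RNA-seq covered 3 experiments with 3 libraries per group. The first compared hematopoietic stem and progenitor cells (HSPCs) of Trp53-null C57BL/6 mice 48 hours after retroviral delivery of a short hairpin RNA against Kmt2d (shKmt2d) or against Renilla luciferase (shRen), an RNA absent from mice. The second compared acute myeloid leukaemia (AML) cells under Kmt2d knockdown with AML cells in which Kmt2d was restored by withdrawal of doxycycline for 4 days. The labels name withdrawal for the restored cells only, and no cells with a control hairpin on and off the drug are among the samples. In RNA-seq, ATAC-seq and CUT&Tag of restored cells, effects of Kmt2d and of the drug's withdrawal therefore cannot be told apart. The third compared AML cells given DZNeP, a methyltransferase inhibitor, with cells given its solvent DMSO. The labels give no dose or duration for DZNeP. ATAC-seq and CUT&Tag for H3K4me1, H3K4me2 and H3K27ac had 2 libraries per group of restored and knockdown AML cells, and CUT&Tag for H3K27me3 had 3. The 40 samples fell into 16 groups, described by 8 tables. Reads per library in the tables, in units of M (mega), ranged from 19.6 M to 24.6 M in HSPCs, from 12.1 M to 17.3 M in the restoration experiment and from 15 M to 16.5 M in the DZNeP experiment. They ranged from 10.1 M to 16 M for ATAC-seq, from 5.04 M to 5.88 M for H3K4me1, from 2.56 M to 4.39 M for H3K4me2, from 2.91 M to 3.96 M for H3K27ac and from 4.36 M to 6 M for H3K27me3. The labels do not say whether replicates were separate cultures or animals, so the p-values may measure technical spread.

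The first comparison asked what loss of Kmt2d changed in HSPCs. Kmt2d itself fell to 3857 ± 1030 after knockdown from 6895 ± 278 in control cells (normalised read counts, mean ± SD, n = 3 per group). Single ribosomal protein genes rose, among them Rpl36, of the large ribosomal subunit, at 17600 ± 2770 against 10900 ± 201. The antiviral GTPase gene Mx1 rose to 2207 ± 96.4 from 1217 ± 91.9, and so did the stress genes Trib3, a pseudokinase, and Ddit3, a transcription factor. Kmt2a, another H3K4 methyltransferase gene, fell to 1606 ± 407 from 3282 ± 101, and its relative Kmt2c fell to 1039 ± 276 from 2130 ± 191.

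**Figure D1:**
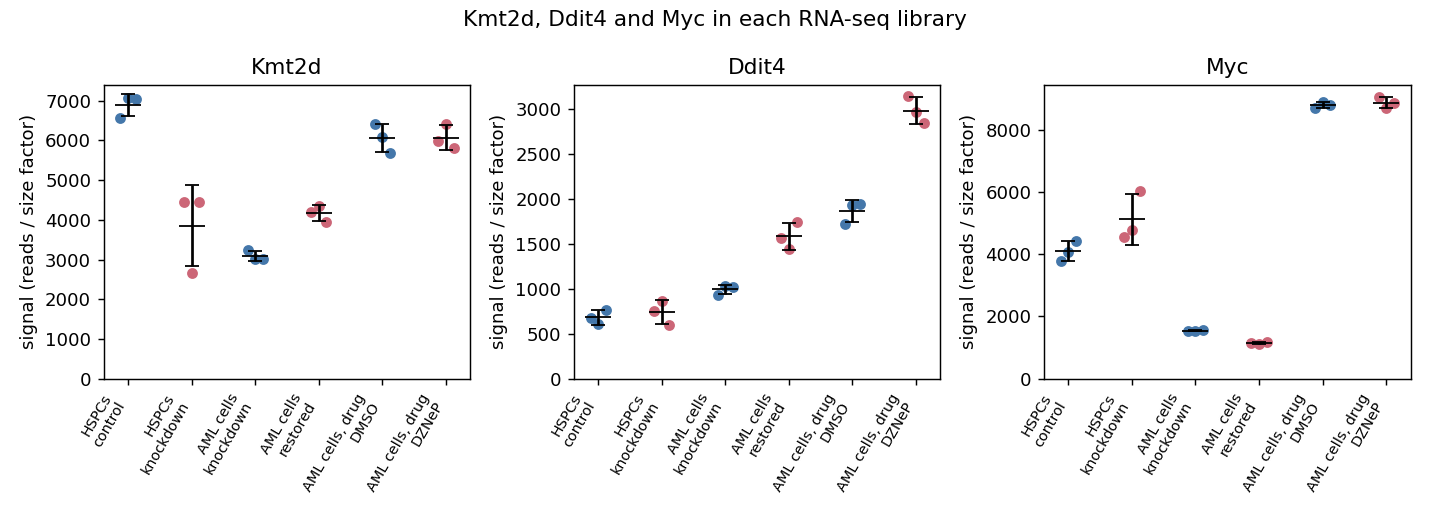
Normalised read counts (reads divided by the size factor of the library, vertical axis from 0) of Kmt2d, Ddit4 and Myc in each RNA-seq library, by group along the horizontal axis. Points are libraries, the long bar is the mean and the whiskers are the SD (n = 3); the Kmt2d mean was 3857 against 6895 in HSPCs and 4163 against 3092 on restoration.

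Of 12528 genes tested with limma, 1872 rose and 1942 fell after knockdown at an adjusted p below 0.05, or 30.4%. The libraries of both groups did not overlap in 46.9% of genes, a share that chance sets at 10% for 3 against 3. The log2 fold change of Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98874077, mm10) was -0.88 (SE 0.17, adjusted p = 0.00762), and knockdown replicate 2 held the lowest value, 2664. Ddit4, an inhibitor of the mTOR kinase (ENSMUSG00000020108, chromosome 10, 59949675 to 59951770), measured 737.1 ± 131 against 681.7 ± 81, a log2 fold change of 0.10 that did not pass the test (adjusted p = 0.63). Without knockdown replicate 2 the value for Ddit4 was -0.01, and without knockdown replicate 3, shRen replicate 2 and shRen replicate 3 it was 0.25, 0.02 and 0.19. Myc, a transcription factor that drives growth (ENSMUSG00000022346, chromosome 15, 61985341 to 61990361), measured 5111 ± 806 against 4096 ± 327 and did not pass the test (log2 0.31, adjusted p = 0.077, and 0.04 with the replicate block), with log2 0.39 and adjusted p = 0.0308 without knockdown replicate 1 log2 0.19 without knockdown replicate 3 and log2 0.12 with the span trend removed. Ezh2, the H3K27 methyltransferase (ENSMUSG00000029687, chromosome 6, 47530274 to 47595270), measured 2219 ± 82.3 against 2061 ± 164 (adjusted p = 0.431), but passed the test with the span trend removed (log2 0.35, adjusted p = 0.0266). Kdm6a, an H3K27 demethylase found in complexes with Kmt2d (ENSMUSG00000037369, chromosome X, 18160862 to 18279936), fell from 990.2 ± 101 to 667.5 ± 137 (log2 -0.58, adjusted p = 0.0177). Its adjusted p was 0.0687 without shRen replicate 1 and 0.0657 without shRen replicate 2, and with the span trend removed Kdm6a was at log2 -0.28 (adjusted p = 0.0942).

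The genes with the largest rises included the chemokine Cxcl3 (log2 1.68), the stress transcription factor Atf3 (1.41), the macrophage elastase Mmp12 (1.25), the ferritin heavy chain Fth1 (1.12) and Rgs1, a regulator of G protein signalling (1.09). Ifi205, Gbp6 and Bcl2a1a rose by log2 1.35, 1.19 and 1.18, but each has close relatives in the mouse genome, so reads may be shared between them. The largest falls included Cbl, a ubiquitin ligase that damps growth factor receptors (2893 ± 332 to 719 ± 440, log2 -2.23), Zbed6 (log2 -2.22, and -1.42 without knockdown replicate 2), Vasn (-2.02), Uhmk1 (-1.80), Ly75 (-1.79), the Argonaute gene Ago2 (-1.71), Lnpep (-1.67) and Hmbox1 (-1.63).

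Of 77 cytosolic ribosomal protein genes measured, 68 rose, none fell and 9 did not pass the test, or 69 rose when adjusted over the list alone (median log2 0.52). Rps14 rose from 16200 ± 865 to 25330 ± 2940 and Rpl12 from 16410 ± 703 to 25520 ± 4310. Among 61 ribosome biogenesis factors 35 rose and 2 fell, or 38 and 2 adjusted over the list alone; the nucleolar proteins Fbl and Nolc1 rose by log2 0.61 and 0.57, Nop16 rose by 0.67, and the large ATPase gene Mdn1 fell by 0.91. In the RNA polymerase I machinery 8 of 15 genes rose and none fell, the same counts when adjusted over the list alone, with the subunits Polr1c and Polr1d at log2 0.59 and 0.47. Polr1d had an adjusted p of 0.0724 without shRen replicate 2. The camera test called these 3 lists as higher (adjusted p = 1.14e-18, 9.77e-10 and 0.00707), against adjusted p = 0.759, 0.759 and 0.633 with an estimated correlation. Fry gave adjusted p = 0.104, 0.0799 and 0.0329, so it called only the last of them. The estimated correlation of the ribosomal protein genes was 0.906, against the preset 0.01. Knockdown replicate 2 stood apart on the first principal component (56.2 against 10.3 and 16 for the other knockdown libraries). The fold changes followed gene span with a Spearman rho of -0.42 over 12307 genes, and the median of the ribosomal protein genes was 0.28 with the span trend removed. Rps14, Rpl12, Polr1c and Mdn1 were then at log2 0.42, 0.36, 0.38 and -0.60 and still called (adjusted p = 0.00868, 0.0163, 0.0172 and 0.0107).

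Of 26 interferon-stimulated genes 18 rose and none fell, the same counts when adjusted over the list alone (median log2 0.60). Mx1, Gbp3 and Gbp2 rose by log2 0.86, 0.86 and 0.92. The list was called as higher (camera adjusted p = 6.34e-10), with adjusted p = 0.586 with an estimated correlation. Of 17 integrated stress response genes 11 rose and none fell, the same counts when adjusted over the list alone, with Trib3 at log2 1.07, the transcription factor Atf5 at 0.93 and Ddit3 at 0.90 (camera adjusted p = 1.31e-05, and adjusted p = 0.511 with an estimated correlation). Of 13 dendritic cell and MHC class II genes 6 rose and none fell, also when adjusted over the list alone, including Bst2 (15300 ± 3500 against 7666 ± 812), H2-Eb1 (log2 1.00) and H2-Ab1 (0.84). That list had a camera adjusted p of 0.0132 and adjusted p = 0.511 with an estimated correlation. Of 17 genes of the KMT2 complexes and H3K4 demethylases 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00327, and adjusted p = 0.759 with an estimated correlation). Fry did not call this list (adjusted p = 0.104), but called the interferon, stress response and MHC class II lists (adjusted p = 0.0144, 0.0104 and 0.0144). Kmt2a and Kmt2c fell by 1.06 and 1.07 on the log2 scale and the H3K4 demethylase gene Kdm5a fell by 0.81 (0.54 with the span trend removed), while Dpy30, a small shared subunit, rose by log2 0.53, with adjusted p = 0.0622 without shRen replicate 1 and 0.0969 without shRen replicate 2. With the span trend removed Kmt2d was at log2 -0.71 (adjusted p = 0.00968) and these 4 lists were still called (adjusted p = 2.42e-10, 0.000389, 0.00375 and 0.00867).

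No other list was called in HSPCs, though single members changed. Of 24 stem and progenitor cell genes 4 rose and 3 fell, with Ly6a (Sca-1) at 10070 ± 1970 against 4922 ± 473. Among 21 granulocyte genes 3 rose and 4 fell, including the receptors Cxcr2 (log2 -0.87) and Csf3r (-0.71). Among 19 monocyte and macrophage genes 6 rose and 4 fell, with the Fc receptor gene Fcgr1 at log2 0.82 and the integrin gene Itgam at -0.87. Of 30 cell cycle genes 3 rose and 6 fell, with Mki67 at log2 -0.59 and the kinase gene Bub1 at -0.50. Of 12 p53 target genes 4 rose and 1 fell in these cells from Trp53-null mice, with Bax at log2 0.62 and Trp53inp1 at -1.02. The negative regulators of mTOR gave 3 rises and 4 falls among 17 genes, and the mTORC1 components and amino acid transporters 4 rises and 1 fall among 20, with Eif4ebp1, a repressor of translation, at log2 0.60. There were 2 falls among 13 mast cell and basophil genes, 2 among 11 erythroid genes and 2 among 6 stromal and endothelial genes. The Polycomb repressive complex 2 list gave 2 falls among 12 genes. No gene of these lists rose. Rises and falls numbered 1 and 0 among 10 megakaryocyte genes, 1 and 0 among 10 B cell genes, 2 and 2 among 18 glycolysis and hypoxia genes, 1 and 1 among 20 cholesterol biosynthesis genes, and 1 and 3 among 9 methionine cycle genes. Only 3 members each of the T and NK cell genes (1 rose, 1 fell) and of the developmental Polycomb target genes (2 rose) were measured, too few for the list test. No mitochondrially encoded gene was listed in any of the RNA-seq tables.

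The count of 3814 genes moved with the control libraries: it was 1949 without shRen replicate 1, 1112 without shRen replicate 2 and 2081 without shRen replicate 3, and 3138 without knockdown replicate 2. Scaling by library totals alone gave 1247 rises and 2180 falls, and removing the span trend gave 1753 rises and 1304 falls, with 2390 of these genes among the 3814. As reported, 406 genes also had an absolute log2 fold change of at least 1, of which 89 rose and 317 fell.

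The second comparison asked what changed in AML cells when Kmt2d returned on withdrawal of doxycycline. Kmt2d rose to 4163 ± 204 from 3092 ± 134 (log2 0.43, SE 0.04, adjusted p = 1.55e-11), Ddit4 rose to 1580 ± 155 from 991.2 ± 49.7 (log2 0.67, SE 0.06, adjusted p = 2.13e-13) and Myc fell to 1139 ± 24.8 from 1540 ± 17.3 (log2 -0.44, SE 0.05, adjusted p = 3.23e-10; n = 3 per group, limma). Cd74, the invariant chain of MHC class II, rose to 1632 ± 179 from 86.86 ± 7.02, and all 11 measured B cell genes rose. Ddx21, a nucleolar RNA helicase gene, fell to 6965 ± 82.6 from 9328 ± 242. The amino acid enzyme gene Asns fell to 1400 ± 44.1 from 2828 ± 76.5, and the glycolytic enzyme gene Pfkp fell to 1776 ± 12.1 from 2733 ± 30.9.

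Of 12020 genes tested 2683 rose and 2709 fell, or 44.9%, and with the span trend removed 1986 rose and 3844 fell. The libraries did not overlap in 50.9% of genes against 10% by chance. Ezh2 rose from 7354 ± 68 to 8870 ± 127 (log2 0.27, adjusted p = 1.83e-08). Kdm6a measured 1068 ± 53.6 against 1077 ± 34 (log2 -0.01, adjusted p = 0.855), with the sign turned without restoration replicate 3 (0.03) and without knockdown replicate 1 (0.01). The largest rises were those of the transcription factor gene Spib (40.21 ± 9.17 to 1205 ± 17.1, log2 4.90), Ms4a1, which encodes CD20 (4.40), Cd74 (4.21), Rapgefl1 (3.23), Snn (3.18), Srpk3 (3.03), H2-Eb1 (2.94) and H2-Aa (2.86). The largest falls were those of Fam78b (-1.33), the adenylate kinase gene Ak4 (-1.25), the protease inhibitor gene Slpi (-1.22), Hs3st2 (-1.11), Gria2 (-1.10), Slc29a3 (-1.07), Etv4 (-1.06) and Gaa (-1.05). A log2 fold change of at least 1 was reached by 481 of the genes that rose and 140 of those that fell.

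All 11 measured B cell genes rose, also when adjusted over the list alone (median log2 0.59), including the receptor chains Cd79b (2760 ± 51.5 to 5564 ± 348) and Cd19 (6331 ± 119 to 10250 ± 300). The camera adjusted p was 1.53e-12, and adjusted p = 0.0497 with an estimated correlation. Of 9 dendritic cell and MHC class II genes 7 rose and 1, Bst2, fell, also when adjusted over the list alone (median log2 1.29, camera adjusted p = 5.31e-11, and adjusted p = 0.0497 with an estimated correlation). Bst2 did not pass the test with DESeq2 (log2 -0.30, adjusted p = 0.13). Of 8 monocyte and macrophage genes 4 rose and none fell, or 5 adjusted over the list alone (camera adjusted p = 0.00968, and adjusted p = 0.108 with an estimated correlation). Irf8, a transcription factor of monocytes, dendritic cells and B cells, rose from 4991 ± 83 to 7779 ± 160, while the protease Ctss (262.9 ± 9.24) and the receptor Cx3cr1 (73.25 ± 5.87) rose to low levels. In all 12 RNA-seq libraries labelled AML the B cell genes together exceeded the granulocyte genes, at 2590 to 5640 per M of library total against at most 4.85. In HSPC libraries the B cell genes gave 39 to 61.5 per M and the granulocyte genes at least 46100. Of the 22 granulocyte genes only Mmp8 (6.143 ± 2.79 against 1.519 ± 1.69) and Lyz2 (5.229 ± 1.66 against 13.63 ± 4.18) were measured in the restoration experiment.

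**Figure D2:**
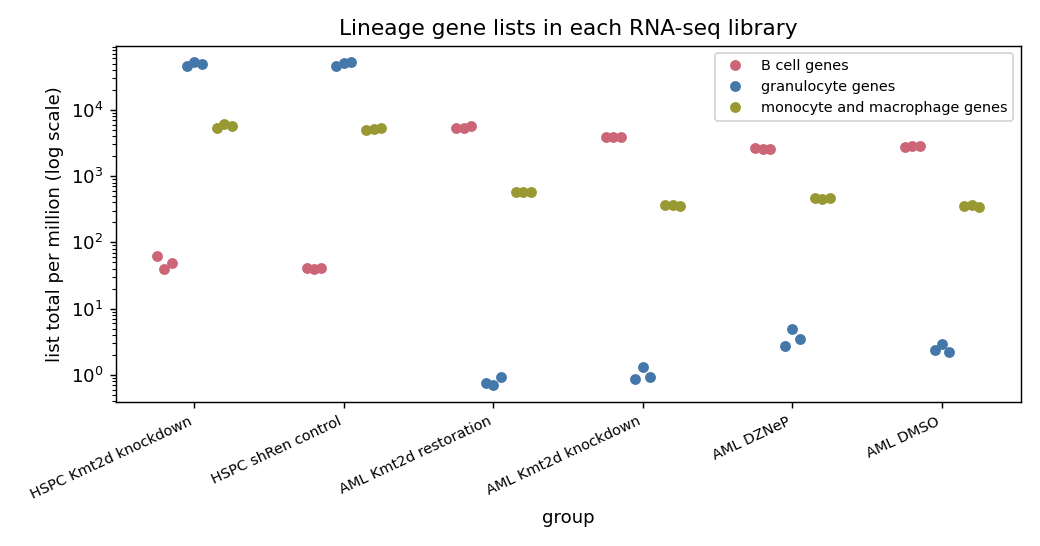
Summed signal of the B cell, granulocyte and monocyte and macrophage genes per M of the library total (vertical log axis) in each RNA-seq library, by group along the horizontal axis. Each point is a library; the 12 AML libraries lie between 2590 and 5640 for B cell genes, and the 6 HSPC libraries between 39 and 61.5.

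Of 77 ribosomal protein genes 69 fell and none rose on restoration, or 71 fell adjusted over the list alone (median log2 -0.19), with Rps2 at 28940 ± 992 against 36010 ± 1610 and Rpl18 at log2 -0.34. Of 61 ribosome biogenesis factors 59 fell and none rose, also when adjusted over the list alone (median -0.35), including Ddx21 (log2 -0.42), Nop16 (-0.49) and Noc2l (-0.39). Of 15 genes of the RNA polymerase I machinery 9 fell and 1 rose, or 10 and 1 adjusted over the list alone, with the subunits Polr1b (-0.58) and Polr1a (-0.41) and the nucleolar factor Tcof1 (-0.33) lower. The camera adjusted p values of these 3 lists were 6.12e-16, 4.33e-25 and 0.00047, against adjusted p = 0.418, 0.0925 and 0.0925 with an estimated correlation. Of 15 integrated stress response genes 10 fell and 2 rose, also when adjusted over the list alone, with Asns (log2 -1.01), Vldlr (-2.01) and the serine pathway gene Shmt2 (-0.51) lower and Ddit4 higher (camera adjusted p = 7.38e-05, and adjusted p = 0.0925 with an estimated correlation). Of 18 glycolysis and hypoxia genes 14 fell and none rose, or 14 and 1 adjusted over the list alone, with Pfkp (-0.62), Pfkl (-0.51) and the hexokinase gene Hk2 (-0.78) lower (camera adjusted p = 3e-07, and adjusted p = 0.108 with an estimated correlation). Of 30 cell cycle genes 16 rose and 2 fell, or 17 and 3 adjusted over the list alone, with the proliferation marker Mki67 (21220 ± 660 to 28810 ± 703), Cenpf (log2 0.42) and Top2a (0.31) higher and Cdc20 (-0.26) lower (camera adjusted p = 0.00125, and adjusted p = 0.108 with an estimated correlation).

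Other lists had members on both sides. The negative regulators of mTOR gave 5 rises and 4 falls among 16 genes, with Ddit4 (0.67), the sestrin gene Sesn3 (0.48) and Pik3ip1 (0.33) higher. The mTORC1 components and amino acid transporters gave 5 rises and 5 falls among 19 genes, with Rragd (0.57) higher and the leucine transporter gene Slc7a5 (-0.67) lower. The Polycomb repressive complex 2 list gave 7 rises among 12 genes, Ezh2 and Phf19 (0.54) included. Its 3 falls included the H3K27 demethylase gene Kdm6b (-0.31), and the camera adjusted p was 0.0946. The KMT2 complexes and H3K4 demethylases gave 5 rises, Kmt2d included, and 6 falls among 17 genes, with Kdm5b at log2 -0.92. The p53 target genes gave 5 rises and 4 falls among 12, with Trp53inp1 at 1.47 and Cdkn1a at 0.54. Among 17 interferon-stimulated genes 3 rose and 4 fell, and the median (0.11) and mean (0.25) log2 fold changes were positive while the camera test pointed downwards (adjusted p = 0.999). Rises and falls numbered 3 and 1 among 8 stem and progenitor cell genes, with Lmo2 at 0.44, 1 and 0 among 6 erythroid genes, 2 and 0 among 5 megakaryocyte genes, 3 and 7 among 20 cholesterol biosynthesis genes, 1 and 2 among 8 developmental Polycomb target genes and 1 and 5 among 9 methionine cycle genes. Too few members for the list test were measured of the granulocyte genes (2, of which 1 rose and 1 fell), mast cell and basophil genes (1, not called), T and NK cell genes (3, of which 1 rose) and stromal and endothelial genes (3, of which 2 rose).

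Of 10921 genes tested in both experiments, 787 rose on knockdown in HSPCs and fell on restoration in AML cells, against 418.6 with no association (odds ratio 3.29, 95% confidence interval 2.95 to 3.67, Fisher's exact test p = 5.9e-101). Another 580 fell on knockdown and rose on restoration, against 380.8 (odds ratio 2.04, interval 1.82 to 2.29, Fisher's exact test p = 1.08e-33). Genes that moved the same way in both were fewer than with no association, with 185 that rose in both against 388.9 (odds ratio 0.37, Fisher's exact test p = 1.56e-42) and 276 that fell in both against 410 (odds ratio 0.56, p = 1.28e-17). At an absolute log2 fold change of at least 1 neither shortfall held. The first reversed to an excess that did not pass the test, with 4 genes that rose in both (odds ratio 3.03, Fisher's exact test p = 0.0518). The second did not pass the test, with 2 genes that fell in both (odds ratio 0.94, Fisher's exact test p = 1). Without an HSPC library the opposite overlaps varied in size, to 425, 173 and 423 genes for the first without shRen replicate 1, 2 and 3, and to 322, 225 and 344 for the second. With the span trend removed they held 970 and 286 genes (odds ratios 3.48 and 1.98), and at an absolute log2 fold change of at least 1 they held 4 and 14 (odds ratios 9.14 and 2.42). Genes are not independent replicates, and the correlation of fold changes across genes was weak (Spearman rho -0.22).

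**Figure D3:**
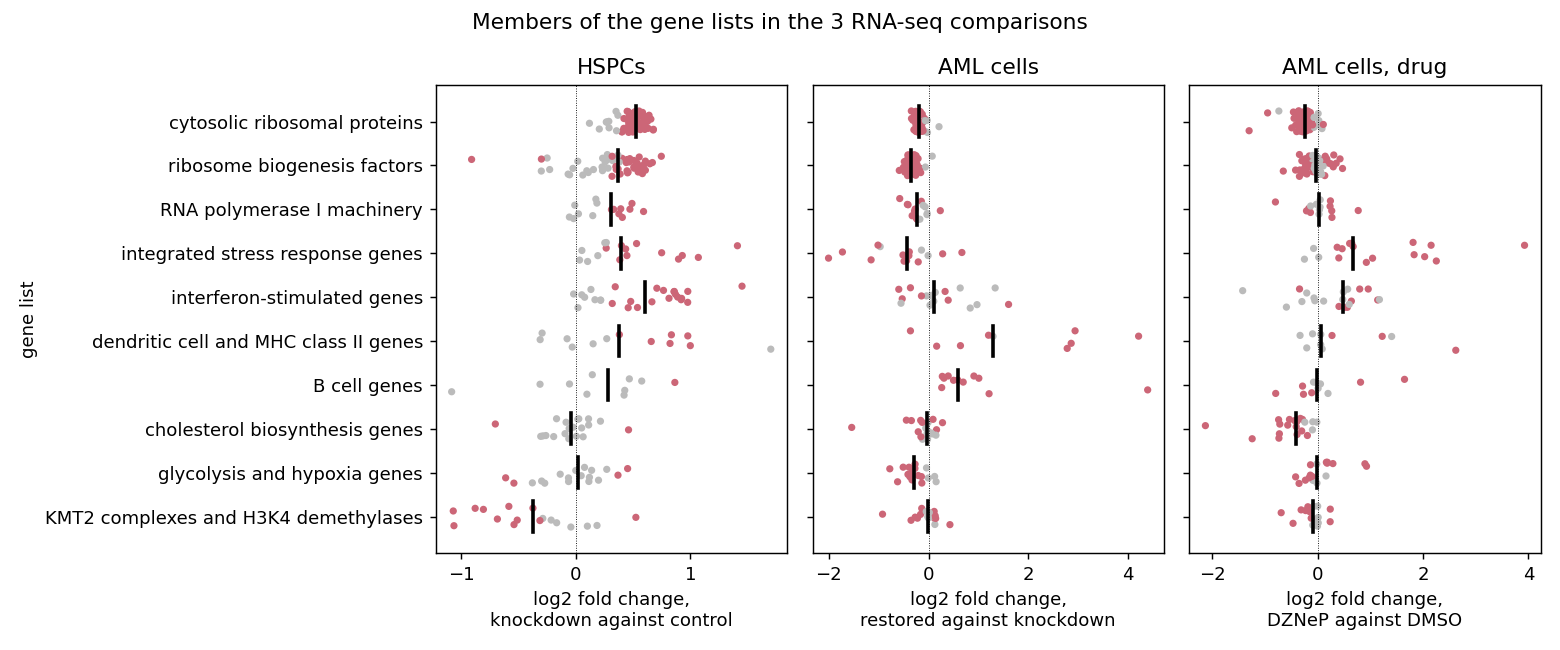
Log2 fold change (horizontal axis) of each measured member of 10 gene lists in the 3 RNA-seq comparisons, with genes past the threshold in red, others in grey and the list median as a black bar. The ribosomal protein median was 0.52 on knockdown in HSPCs, -0.19 on restoration and -0.24 with DZNeP; Rpl41 was at 0.11 with DZNeP and turned to -0.03 with the span trend removed.

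The third comparison asked what DZNeP changed in AML cells. Ddit4 rose to 2977 ± 151 from 1865 ± 122 (log2 0.68, SE 0.05, adjusted p = 3.66e-19) and the stress transcription factor Atf4 rose to 7141 ± 68.5 from 3759 ± 162 (n = 3 per group). Kmt2d measured 6072 ± 311 against 6061 ± 360 (log2 0.00, SE 0.04, adjusted p = 0.956) and Myc 8863 ± 171 against 8782 ± 91.5 (log2 0.01, adjusted p = 0.764). The LDL receptor gene Ldlr fell to 834 ± 24.4 from 1970 ± 23.6 and Hmgcr, which encodes the rate-limiting enzyme of cholesterol synthesis, fell to 3071 ± 37.1 from 5123 ± 32.5. The ribosomal protein gene Rpl3 fell to 12190 ± 279 from 23480 ± 748.

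Of 12558 genes tested 3134 rose and 3182 fell, or 50.3%. Scaling by library totals alone gave 4237 rises and 2263 falls, and removing the span trend gave 2186 rises and 4306 falls. The libraries did not overlap in 56.3% of genes against 10% by chance. Ezh2 fell to 5110 ± 216 from 6176 ± 29.7 (log2 -0.27, adjusted p = 3.03e-09) and Kdm6a fell to 825.1 ± 37.2 from 964.2 ± 32.9 (log2 -0.23, adjusted p = 0.000743). The largest rises were those of Dntt, the terminal transferase gene of early lymphocytes (61.15 ± 7.64 to 681 ± 20.6, log2 3.46), Colq (2.55), Kcnmb1 (1.76), the DNA polymerase gene Poli (1.72), Fndc9 (1.59), the alanine transaminase gene Gpt2 (1.58) and Arl4a (1.37). Hist1h4i rose by log2 2.99, but histone H4 genes are near copies of each other, so reads may be shared between them. The largest falls were those of Adssl1 (-1.86), Rgp1 (-1.83), Gas5 (3971 ± 95.6 to 1149 ± 15.1, log2 -1.79), the transporter gene Slc22a8 (-1.60), Plekhg2 (-1.49), Snhg5 (-1.47), Btbd2 (-1.46) and Fam120c (-1.40). Gas5 and Snhg5 are host genes of small nucleolar RNAs. With library totals alone Myc passed the test (log2 0.10, adjusted p = 0.0094), while with the span trend removed Myc was at -0.12 (adjusted p = 0.000618) and Kmt2d at -0.05. Without DZNeP replicate 2 Kmt2d was at -0.04, as it was without DMSO replicate 3.

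Of 17 integrated stress response genes 14 rose and none fell, also when adjusted over the list alone (median log2 0.68), including Asns (2104 ± 77.3 to 4340 ± 161), Atf4 (0.93) and Ddit4 (camera adjusted p = 2.62e-10, and adjusted p = 0.194 with an estimated correlation). Of 20 cholesterol biosynthesis genes 16 fell and none rose, or 17 adjusted over the list alone (median -0.40), including Ldlr (-1.24), Hmgcr (-0.74) and Srebf2, a transcription factor of the pathway (-0.71; camera adjusted p = 7.4e-10, and adjusted p = 0.146 with an estimated correlation). Of 77 ribosomal protein genes 69 fell and 1 rose, also when adjusted over the list alone (median -0.24), including Rpl3 (-0.95), Rpl10 (-0.46) and Rpl28 (-0.49; camera adjusted p = 2.04e-20, and adjusted p = 0.362 with an estimated correlation). The gene that rose, Rpl41 (log2 0.11, adjusted p = 0.0253), turned to -0.03 with the span trend removed and lost its call with DESeq2 (adjusted p = 0.412), with the replicate block (0.0696), with log2(value + 0.1) (0.0684), and, in log2 values, without DZNeP replicate 1 (0.06), without DZNeP replicate 2 (0.10) and without DMSO replicate 1 (0.03). Its value was 0.18 without DZNeP replicate 3 and 0.17 without DMSO replicate 3.

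The other lists were not called. Among 61 ribosome biogenesis factors 12 rose and 21 fell, with Npm1 (-0.65) lower and Rrs1 (0.47, and 0.31 with the span trend removed) higher. The RNA polymerase I machinery gave 5 rises and 4 falls among 15 genes, with Cd3eap at 0.77 and Taf1d at -0.80. The negative regulators of mTOR gave 9 rises and 5 falls among 16, with the kinase gene Stk11 (0.60) and the sestrin gene Sesn2 (1.83) higher and Tsc2 (-0.26) lower. The mTORC1 components and amino acid transporters gave 8 rises and 6 falls among 20, with Slc3a2 (0.67), Slc7a5 (0.59) and Eif4ebp1 (0.80) higher and Slc1a5 (-0.44) lower. The Polycomb repressive complex 2 list gave 2 rises and 6 falls among 12 genes (camera adjusted p = 0.107). Phf19 (-0.66) and Ezh2 of the complex were lower, and so was the H3K27 demethylase gene Kdm6b (-0.67). The KMT2 complexes and H3K4 demethylases gave 2 rises and 7 falls among 17, with Setd1b (-0.69) and Kmt2a (-0.46) lower. Of 9 methionine cycle genes 1 rose and 3 fell, namely Mat2a (-0.71), the S-adenosylhomocysteine hydrolase gene Ahcy (-0.57), whose product DZNeP inhibits, and Ahcyl1 (-0.42). Of 11 B cell genes 2 rose and 4 fell, with Cd79a at 5291 ± 71.7 against 9169 ± 150. Of 9 monocyte and macrophage genes 6 rose and none fell (camera adjusted p = 0.0689). Rises and falls numbered 5 and 2 among 11 stem and progenitor cell genes, with Myb at 0.26, 3 and 1 among 7 erythroid genes, 0 and 1 among 5 megakaryocyte genes, 3 and 0 among 10 dendritic cell and MHC class II genes, 6 and 12 among 30 cell cycle genes, with Cdc20 at -0.65, and 6 and 2 among 12 p53 target genes. They numbered 7 and 1 among 20 interferon-stimulated genes, 6 and 7 among 17 glycolysis and hypoxia genes and 2 and 0 among 9 developmental Polycomb target genes. The median and the mean log2 fold change differed in sign for the B cell genes (-0.01 and 0.11) and for the glycolysis and hypoxia genes (-0.02 and 0.07), both with a downward camera direction. Too few members for the list test were measured of the granulocyte genes (3, none called), mast cell and basophil genes (2, of which 1 rose), T and NK cell genes (4, of which 1 rose and 1 fell) and stromal and endothelial genes (4, of which 2 rose).

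Of 11789 genes tested in both AML experiments 788 rose with DZNeP and on restoration, against 666 with no association (odds ratio 1.36, 95% confidence interval 1.23 to 1.49, Fisher's exact test p = 9.82e-10), and 1067 fell in both, against 726.8 (odds ratio 2.17, interval 1.97 to 2.38, Fisher's exact test p = 3.61e-60). With the span trend removed 443 rose in both and 1987 fell in both (odds ratios 1.47 and 2.53). At an absolute log2 fold change of at least 1, 85 rose in both and 7 fell in both (odds ratios 8.3 and 3.9). Ddit4 was among the genes that rose in both. Overlaps of genes that moved in opposite directions in these 2 experiments were not tested. The odds ratios alone therefore do not show that shared calls went the same way more often than opposite ways. Across all genes the fold changes were nearly unrelated (Spearman rho 0.10).

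Chromatin was compared between restored and knockdown AML cells to ask where marks and accessibility changed when Kmt2d returned on withdrawal of doxycycline. H3K4me1, the mark that Kmt2d places, changed in both directions, in 27092 of 40802 regions with limma and in 19040 of 39219 with DESeq2. The region at Smarcd1 and Gm16537 on chromosome 15 (99712746 to 99715054) rose to 480.9 ± 28.6 from 29.41 ± 0.0331 (log2 3.99, SE 0.14, n = 2 per group), and a region in Dtx2 (chromosome 5, 136018871 to 136020085) rose to 521.1 ± 22.4 from 33.94 ± 6.44. At ribosomal protein genes 85 of 106 regions fell and 5 rose. Among all 40802 regions 13946 fell, and of those within 2 kb of a gene 12239 fell, 9917 rose and 9529 were not called. Falls outnumbered rises in most gene lists, among them developmental Polycomb target genes (27 of 38 fell), cholesterol biosynthesis genes (23 of 37) and KMT2 complex and H3K4 demethylase genes (19 of 35). Rises outnumbered falls at stem and progenitor cell genes (19 and 18), megakaryocyte genes (6 and 2) and T and NK cell genes (5 and 2). They also did at granulocyte genes (4 and 2) and at stromal and endothelial genes (3 and 1). No list-level test was run on regions. A region in the body of Kmt2d itself (chromosome 15, 98867491 to 98870010) fell to 154.5 ± 17.9 from 326.7 ± 34.3.

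Of 40802 H3K4me1 regions 13146 rose and 13946 fell, or 66.4%, against 8980 and 10060 with DESeq2, and the libraries did not overlap in 83% of regions, a share that chance sets at 33.3% for 2 against 2. Further large rises lay at Thop1 (chromosome 10, 81075701 to 81077827, log2 3.63), Bcl9l (chromosome 9, 44499465 to 44500418, 3.59) and Ak1 (chromosome 2, 32634452 to 32635363, 3.58). The largest falls lay at Ska2 (chromosome 11, 87111668 to 87112538, -2.56), Zfc3h1 (chromosome 10, 115391258 to 115392024, -2.45), Ccnb1 (chromosome 13, 100783810 to 100785329, -2.43), Cpped1 and Gm9961 (chromosome 16, 11908153 to 11909420, -2.40) and Dxo, Skiv2l and Stk19 (chromosome 17, 34837617 to 34838400, -2.38). Regions that fell lay within 2 kb of a gene in 87.8% of cases and overlapped an H3K4me2 region in 87.5%, against 75.4% and 34.6% of those that rose. At ribosome biogenesis factors 72 of 83 regions fell and 7 rose, at cell cycle genes 40 of 52 fell and 5 rose, and at B cell genes 21 of 45 fell and 13 rose. At Ddit4 a region just outside the gene (chromosome 10, 59952111 to 59954023) rose to 226.7 ± 13.1 from 177.5 ± 16.4 (adjusted p = 0.0033, 0.0714 without restoration replicate 2 and 0.0898 with DESeq2). The region over Ddit4 (59947653 to 59950530) measured 176.5 ± 33.3 against 155 ± 28.9 and did not pass the test (log2 0.18, adjusted p = 0.171). That value was -0.01 without restoration replicate 2 and without knockdown replicate 1, and passed the test at 0.38 without restoration replicate 1 and without knockdown replicate 2 (adjusted p = 0.0251 and 0.0126). At Myc (chromosome 15, 61988841 to 61991683) the mark fell to 74.36 ± 7.66 from 100.5 ± 18.8 (log2 -0.42, adjusted p = 0.0162), with adjusted p = 0.153 without restoration replicate 2 and 0.178 with DESeq2, and log2 -0.23 and adjusted p = 0.31 without knockdown replicate 1. At Ezh2 2 of 3 regions fell, and at Kdm6a 1 of 3 fell (adjusted p = 0.00553), with log2 -0.43 and adjusted p = 0.138 without restoration replicate 1 and 0.0933 without knockdown replicate 2, and 0.134 with DESeq2.

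H3K4me2 rose in 5253 of 26019 regions and fell in 2123, or 28.3%, with 65.5% of regions not overlapping between groups against 33.3% by chance. It rose most at Thra (chromosome 11, 98750258 to 98751072, 115.3 ± 9.94 against 11.72 ± 2.8, log2 3.21), Ak8 (chromosome 2, 28769904 to 28770731, 3.03), Runx3 (chromosome 4, 135135452 to 135137094, 2.84), Gm13790 (chromosome 5, 114550585 to 114554122, 2.84) and the kinase gene Fgr (chromosome 4, 132972046 to 132972944, 2.79). It fell most at Src (chromosome 2, 157447837 to 157448993, 4.573 ± 5.06 against 114.6 ± 2.56, log2 -4.76), Macf1 and D830031N03Rik (chromosome 4, 123404970 to 123407029, -1.15), Tpm1 (chromosome 9, 67047463 to 67049196, -1.13), Six1 (chromosome 12, 73044567 to 73046224, -1.11) and Fgf5 (chromosome 5, 98253709 to 98254841, -1.08). With DESeq2, which compared 1 restored library with 2 knockdown libraries, the falls at Tpm1, Six1 and Fgf5 did not pass the test. Of the regions that rose 99.6% overlapped an H3K4me1 region and 96.5% an H3K27ac region. At ribosomal protein genes 31 of 91 regions fell and none rose by limma, and at B cell genes 10 of 29 rose and none fell; both counts of 0 come from the limma test alone, with no list-level test run on regions. At Kmt2d 1 of 4 regions fell (chromosome 15, 98853946 to 98854572, 7.682 ± 3.18 against 21.36 ± 3.08, adjusted p = 0.0378). It lost its call without knockdown replicate 1 (0.197), without knockdown replicate 2 (0.0679) and without restoration replicate 1 (0.218). The regions at Ddit4, Myc, Ezh2 and Kdm6a did not pass the test, the smallest adjusted p being 0.0775 at Ddit4; at Kdm6a the log2 value was -0.24, and it was -0.44 with adjusted p = 0.0176 without restoration replicate 1 and -0.05 with adjusted p = 0.834 without restoration replicate 2. With library totals alone a region at each of Ddit4, Myc, Ezh2 and Kdm6a passed as lower (adjusted p = 0.0061, 0.0194, 0.0118 and 0.0287). With edgeR and DESeq2, which left out restoration replicate 2, most falls lost their calls. The smaller set of libraries and the change of method cannot be told apart there. Library totals alone gave 5059 rises and 3790 falls. Without restoration replicate 2 the test gave 4622 regions, 3706 of them rises.

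H3K27ac, a mark of active promoters and enhancers, rose in 3890 of 37918 regions and fell in 2772, or 17.6%, with 55% of regions not overlapping between groups against 33.3% by chance. At an absolute log2 fold change of at least 1, 1315 regions rose and 69 fell. The largest rises lay at Accsl (chromosome 2, 93880579 to 93882537, 60.03 ± 5.55 against 7.037 ± 0.88, log2 2.93), Eya2 (chromosome 2, 165653168 to 165655487, 2.89), Hcn2 (chromosome 10, 79728132 to 79730169, 203.6 ± 24.2 against 32.73 ± 2.96), a region with no gene within 2 kb (chromosome 4, 134041915 to 134043342, 2.58) and Rtn4rl2 (chromosome 2, 84882781 to 84884009, 2.58). The largest falls lay at Gm31887 (chromosome 13, 19184917 to 19186921, -1.75, -1.01 without restoration replicate 1, and adjusted p = 0.126 with DESeq2), a region with no gene within 2 kb (chromosome 14, 50061784 to 50062905, -1.70), Esr1 (chromosome 10, 4991925 to 4992338, -1.56, and -1.01 without restoration replicate 1), Cdh17 (chromosome 4, 11793746 to 11795170, -1.44) and a further region with no gene within 2 kb (chromosome 19, 4490835 to 4491836, -1.43). At Myc (chromosome 15, 61983800 to 61988085) H3K27ac fell to 344.8 ± 8.95 from 440 ± 22.3 (log2 -0.35, adjusted p = 0.000719, and 0.0515 without knockdown replicate 1). At Ezh2 (chromosome 6, 47593796 to 47596081) it fell to 609.2 ± 32.2 from 719.8 ± 5.77 (adjusted p = 0.00616, 0.0656 without knockdown replicate 1, 0.189 without restoration replicate 2 and 0.0921 with DESeq2). At Ddit4 the signal was 760.2 ± 1.34 against 806.7 ± 23.7 and did not pass the test (adjusted p = 0.437), and neither did the regions at Kmt2d and Kdm6a. The count of regions was 4421, 4337 and 4123 without restoration replicate 1, restoration replicate 2 and knockdown replicate 1, and 2242 with DESeq2, with 1573 rises and 669 falls.

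The ATAC-seq regions together covered 1901 Mb, against 69.1 Mb for H3K4me1. Those not called had a median signal of 5.06, so counts and shares here are not of accessible sites alone. Accessibility passed the test at 2 regions, both lower after restoration. The first lay on chromosome 16 (25010381 to 25016330), with no gene within 2 kb, and fell to 145.2 ± 43.6 from 804 ± 64.7 (log2 -2.49, adjusted p = 0.00105). The second lay in Hdac9, a histone deacetylase gene on chromosome 12 (34228901 to 34234220), and fell to 13.28 ± 3.13 from 62.45 ± 1.57 (log2 -2.17, adjusted p = 0.0193). With log2(value + 0.1) the adjusted p values were 0.539 and 0.937, the first had 0.408 with the replicate block and the second 1 with DESeq2. None of 730611 regions rose by limma, while 33411 had an unadjusted p below 0.05, edgeR counted 241 rises and 20 falls and DESeq2 1 fall. In simulated data at this size no 2-fold change was recovered from 705284 regions, and with a mean of at least 20 the limma test gave 160 rises and 11 falls. Calls rested on single libraries, with 57 regions without restoration replicate 1, 258 without restoration replicate 2, and 0 without knockdown replicate 1 or without knockdown replicate 2. At Ddit4 and Myc the regions measured 1166 ± 351 against 1364 ± 26 and 1167 ± 314 against 1249 ± 21, with adjusted p = 0.985 and 0.99. The libraries did not overlap in 32.9% of regions, against 33.3% by chance.

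H3K27me3, the mark placed by Ezh2, rose in 50 of 87311 regions and fell in 13, while 8420 had an unadjusted p below 0.05. It rose at Cnn1 (chromosome 9, 22107533 to 22108424, 43.65 ± 8.09 against 16.51 ± 8.42, n = 3 per group), Fcrla (chromosome 1, 170928519 to 170928892, log2 1.39), Bmp7 (chromosome 2, 172901387 to 172901746, 1.26), a region of chromosome 10 with no gene within 2 kb (81553850 to 81554276, 112.8 ± 11.6 against 46.73 ± 5.71) and Calhm2 (chromosome 19, 47133200 to 47133460, 1.18). The calls at Fcrla, Bmp7, Cnn1 and Calhm2 were lost without restoration replicate 2 (adjusted p = 0.232, 0.377, 0.123 and 0.207). Fcrla and Bmp7 also lost them without restoration replicate 3 (0.175 and 0.149) and without knockdown replicate 2 (0.123 and 0.14), and Fcrla without restoration replicate 1 (0.14). The largest falls lay at Hbb-bs, Hbb-bt, Tmsb4x, Malat1 and S100a8, with wide spreads between libraries (at Hbb-bs 36.46 ± 63.2 against 272.6 ± 197). The limma SE at Hbb-bs was 0.234, so it does not measure the spread between the libraries of that region. With DESeq2 5 regions rose and 0 fell, so each of these falls was lost (adjusted p = 1), as were the rises at Cnn1, Fcrla, Bmp7 and Calhm2 (1 for each). Fcrla and Bmp7 also lost their calls with edgeR and TMM scaling (0.17 and 0.102). None of the 132 regions at developmental Polycomb target genes passed the limma test (median log2 0.23), and none was present at Ddit4, Myc or Kmt2d. The libraries did not overlap in 14.8% of regions, against 10% by chance. The count was 26, 18, 31 and 35 without restoration replicates 1, 2 and 3 and knockdown replicate 2, 36 with library totals alone (20 rises and 16 falls), 30 with edgeR and 5 with DESeq2.

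Marks at genes were then set beside expression in the same AML cells. At genes that rose on restoration the median log2 fold change of H3K27ac was 0.06 (2521 genes), against -0.14 at genes that fell (2546 genes). For H3K4me1 the medians were -0.16 and -0.86, a difference of 0.70, and for H3K4me2 they were 0.01 and -0.18, a difference of 0.19. Accessibility, averaged over all ATAC-seq regions of a gene and not over accessible sites alone, differed by 0.06 between the groups of genes. Each of these 4 differences had a permutation p of 1e-05 (two-sided, 100000 label shuffles across genes), the smallest the shuffles can give, or 1.25e-05 after Benjamini-Hochberg adjustment over the 5 marks. For H3K27me3 the medians were 0.12 and 0.12, and the difference of 0.002 (permutation p = 0.717) ranged from -0.01 to 0.012 with any library of H3K27me3 or RNA-seq left out. Genes are not independent replicates. The shuffles move labels between genes and not between libraries, so their p does not measure the spread between libraries. Accessibility had the same p, though its libraries did not overlap in 32.9% of regions, against 33.3% by chance. Across regions that overlap, fold changes of H3K4me1 went with those of H3K4me2 (Spearman rho 0.67) and of H3K27ac (0.65), and less with those of H3K27me3 (0.004).

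**Figure D4:**
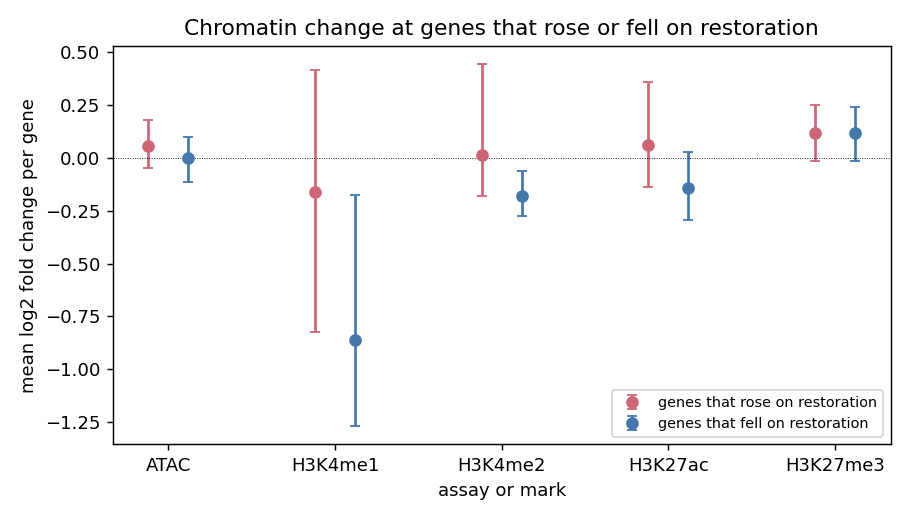
Log2 fold change of each mark or of accessibility on restoration, averaged over the regions of a gene (vertical axis), for genes that rose (red) or fell (blue) in RNA-seq, by assay along the horizontal axis. Points are medians and whiskers run from the lower to the upper quartile over genes; the H3K4me1 medians are -0.16 and -0.86 and the H3K27me3 medians are 0.12 and 0.12.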

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

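Alternatives on recovered reads with edgeR and TMM scaling, on the libraries of the count tests, on regions with a mean of at least 20 and with the span trend removed were chosen after seeing the data, as was leaving out libraries for overlaps and marks at genes. Regions at promoters and outside them were not compared, because the tables hold no such annotation. Replicate numbers did not pair samples: correlations of deviations between libraries of the same number ran from -0.205 to 0.17 in HSPCs and from -0.076 to 0.079 elsewhere. Where a count or sign moved and no reason is given, the cause was not tested.

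With an absolute log2 fold change of at least 1, counts were 406, 621 and 734 genes on knockdown, on restoration and with DZNeP, and 13736 H3K4me1, 2720 H3K4me2, 1384 H3K27ac and 14 H3K27me3 regions. Rises and falls among these genes numbered 89 and 317 on knockdown, 481 and 140 on restoration and 554 and 180 with DZNeP. Among regions they numbered 7081 and 6655 for H3K4me1, 2534 and 186 for H3K4me2, 1315 and 69 for H3K27ac and 7 and 7 for H3K27me3. The odds ratio of genes that rose on knockdown and on restoration was then 3.03. With an estimated correlation 0, 2 and 0 lists were called, and with fry 4, 16 and 19. The 4 on knockdown left out the ribosomal proteins, the ribosome biogenesis factors and the KMT2 complexes and H3K4 demethylases.

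The replicate block as a paired fit gave 3874, 5173 and 6074 genes and 27083, 7676 and 6929 regions of H3K4me1, H3K4me2 and H3K27ac, near the counts reported, and 1 ATAC-seq and 36 H3K27me3 regions. ATAC-seq gave 0 regions with log2(value + 0.1), 8 with log2(value + 5), 227 with library totals, 261 with edgeR and TMM, 181 with edgeR and RLE, 1 with DESeq2 and 171 at a mean of at least 20. H3K27me3 gave 36 with library totals, 30 with edgeR and TMM, 30 with RLE, 5 with DESeq2 and 31 on the libraries of the count tests. H3K4me2 gave 1308 with DESeq2 and 4622 on the libraries of the count tests, and H3K27ac 2242 with DESeq2.

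With each library left out in turn, counts ran from 1112 to 4567 genes on knockdown, 4753 to 5163 on restoration and 5678 to 5911 with DZNeP. They ran from 0 to 258 regions for ATAC-seq, 23285 to 24704 for H3K4me1, 4622 to 6288 for H3K4me2, 4123 to 4566 for H3K27ac and 18 to 79 for H3K27me3. Called lists ran from 7 to 8, 9 to 9 and 3 to 4. The odds ratios of opposite calls ran from 2.83 to 4.05 and from 1.74 to 2.59. The H3K27me3 difference at genes ran from -0.01 to 0.012.

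Some values changed sign. The called rise of Rpl41 with DZNeP became -0.027 with the span trend removed, and the others below were uncalled as reported. Ddit4 on knockdown was -0.171 with the span trend removed and ran from -0.014 to 0.245 with libraries left out. Kdm6a on restoration ran from -0.044 to 0.027. With DZNeP, Kmt2d ran from -0.042 to 0.044 and was -0.046 with the span trend removed, and Myc ran from -0.001 to 0.027 and was -0.122. The H3K4me2 region 15 98868802 98871101 at Kmt2d was at 0.001, 0 and 0.001 with edgeR and TMM, edgeR and RLE and DESeq2. The H3K4me1 region 10 59947653 59950530 at Ddit4 ran from -0.007 to 0.378, and the H3K27ac region 6 47578765 47579404 at Ezh2 from -0.756 to 1.337, with libraries left out.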

Other observations

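Tests for a majority of cells like the HSPCs, for single swapped libraries, for another lineage of the AML cells and for a library that stands apart were chosen after the result was seen.

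B cell genes were high in the libraries labelled AML. B-lineage cells mixed into a majority of myeloid cells like the HSPCs are excluded, since the highest AML library held 0.116 of the monocyte and macrophage signal of the lowest HSPC library (583 against 5020 per M, with Irf8 alone at 540 in restored cells and at most 58.6 in HSPCs), below the 1/2 that a majority needs, and at most 4.85 against 46100 per M for granulocyte genes. A majority of myeloid cells in which these genes are silent cannot be told apart from cells with a B-lineage programme, since H3K27ac per kb at both lists was 0.709 of that at B cell genes (36.5 over 5 granulocyte and 110 over 14 monocyte regions against 128 over 48), a ratio that says little, as the monocyte list holds Irf8, a B cell factor too. Single swapped libraries are excluded, since the lowest AML library held 42.2 times the B cell signal of the highest HSPC library. Another lineage than the label says cannot be told apart either, as 12 of 12 AML libraries had more B cell than granulocyte signal and no library of known lineage is present.

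Ribosomal protein genes were higher after knockdown in HSPCs. The median fell from 0.523 to 0.283 with the span trend removed (SE 0.079, camera adjusted p = 4.57e-11), so a gene length trend cannot be told apart from a change of these genes. A margin of 1 SE was added after this value was seen; without it the bound written beforehand, 1/2 of the median, was met narrowly and would have excluded the trend. Knockdown replicate 2, which stands apart, does not account for the rise, since the median without it was 0.38 (SE 0.08), above 1/2 of 0.523 by more than that margin.

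H3K4me1 changed in 27092 of 40802 regions with limma and in 19040 of 39219 with DESeq2. A difference in signal to background that follows mean signal is excluded. With each library's trend on mean signal removed 27040 regions against 27092 were called (Spearman rho -0.024). The test cannot see a background difference that is unrelated to mean signal, such as one that acts on some kinds of region more than on others. The other splits of the 4 libraries called 0 regions, but each mixed the groups, which keeps that count low whatever the spread. The libraries did not overlap in 83% of regions, against 33.3% by chance. That share does not use or measure the fitted spread, so it cannot show whether the fit took the spread too small. A spread between cultures that these libraries may not hold cannot be told apart from a wide change.

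The groups of 6 libraries allow 10 splits, too few to reach 0.05. As many as the real grouping were called in 1 split for genes in HSPCs (3814, highest other 0), 1 for genes on restoration (5392, highest other 0), 1 for genes with DZNeP (6316, highest other 0) and 1 for H3K27me3 regions (63, highest other 7). For gene lists it was 6 in HSPCs (7, highest other 9), 1 on restoration (9, highest other 6) and 6 with DZNeP (3, highest other 5). The real grouping thus did not stand out for the lists in HSPCs and with DZNeP. For the other counts this check cannot decide between chance and a real grouping, as 10 splits are too few. The limma calls do not rest on it. Each other split also mixed the groups, which keeps counts of genes and regions low. Another arrangement of the HSPC libraries called more lists than the real one.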
